A study of Zea mays with 6 samples.

How the data were processed

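RNA of 6 pools was measured, 3 of DpDf plants and 3 of wild-type siblings, each of 8 seedlings of 14 days. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin by a one-cycle cDNA synthesis kit, and each pool was hybridised to its own array. The authors deposited linear intensity values, 1 per probe set and array, for 17621 probe sets and 113 controls. Per the submitters' processing notes, GCOS 1.2 and GCRMA were used, with the role and order of each not given. Scaling and background steps are not given in the sources used here, and the linear scale was read from the values, which were positive and strongly skewed. On 5 arrays the deposited intensities shared nearly the same distribution (10th percentile 69.58 to 73.71), whereas that of wild type replicate 3 was narrower (10th percentile 104.2). An array has no read depth, so the precision rests on the number of arrays.

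Values were turned into log2(intensity + 1), control probe sets were set aside, and a probe set was kept where at least 3 of the 6 arrays reached their own 40th percentile. This kept 10661 probe sets, or 60.5%. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no block), with Benjamini-Hochberg adjustment over all probe sets kept and an adjusted p under 0.05 as the threshold. The design, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. Because 1 array stood apart, each result is also given without it, which was among the settings chosen beforehand.

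Gene names came from the platform table for the probe sets, updated through gene identifiers with the RefSeq table of the assembly Zm-B73-REFERENCE-NAM-5.0. A single gene symbol was found for 1452 probe sets, several for 1 and none for 16168, and nothing was named from the last 2 kinds. Of 1108 gene identifiers 1060 matched that table. As the array names no genome build, the assembly served only for names and for the order and membership of genes on chromosomes. The short arm of chromosome 5 was taken as the genes in the first 40% of the chromosome and the tip of chromosome 6 as those in the first 3%, with the probe set of highest mean standing for each gene. Only 820 genes were named and kept, 790 of them placed, so most of the transcripts measured belong to no gene group here.

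Gene sets were tested with camera (preset correlation 0.01), beside camera with an estimated correlation and fry, which tests whether the genes of a set move 1 way without comparing them with other genes. For the short arm, adjusted over the same 11 parts of the genome, fry did not pass with all 6 arrays (adjusted p = 0.108) and passed without wild type replicate 3 (adjusted p = 0.00995). Tested alone, as fixed beforehand, it passed 0.05 with fry in both settings. These 11 parts are the 10 chromosomes with chromosome 5 taken in 2, a family of tests added after the data were seen. Lists were matched by symbol and synonym, because no gene descriptions were used here, and 15 of the 25 lists had fewer than 5 genes and were not tested. A single value per array was compared by a two-sided exact permutation test, which with 3 against 3 arrays cannot go below p = 0.1. Bootstrap intervals used 10000 resamples of genes. Genes are not independent replicates, so these intervals leave out the spread between pools.

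Genes were named by a fixed rule among probe sets with an adjusted p under 0.05 whose values in a group all lay above those of the other. It took the 10 higher and 10 lower of largest difference outside the arm, the 8 largest on the arm, called genes of the chromosome 6 tip up to 5, probe sets at background in 1 group only up to 6, and up to 4 members of each list reported by smallest p, and unnamed probe sets, at most 2 higher and 2 lower besides others of the same cluster, given without their ID. The rule was applied to the fit of all 6 arrays and to that without wild type replicate 3. Probe sets at background in 1 group only lay under the 40th percentile on all its arrays and over the 60th on all of the other group, with an adjusted p under 0.05. The 40th percentile of the arrays, 8.28 to 8.33 on the log2 scale, is a set bound, and a probe set under it may still hold signal. Where every array of a group lay under its own 40th percentile, the probe set was taken as not above background there, and only a lower bound is given. It is the mean log2 value of the other group minus the mean of each array's 40th percentile, written as at least so many fold. This held in wild type for 2 of the 3 probe sets called with all 6 arrays and, without wild type replicate 3, for 27 of 355, with 2 more in DpDf.

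Per the labels, pools of the same replicate number came from the same planting of siblings, so the numbers pair the pools. The deviations of paired pools from their group means correlated at 0.076, -0.164 and 0.195, and the fit with the replicate number as a block called 3 probe sets. The fits were tested on simulated data with 200 changed probe sets among 10661. At 4-fold 95.5% were recovered with all 6 arrays and 100% without wild type replicate 3, with 1 and 10 false calls. Probe sets varied independently there, with no 3' over 5' difference between groups. For camera, 20 simulated data sets with no shift of the arm gave 0 calls, and 20 with a log2 shift of 0.4 gave 20. These data sets held independent genes and no array that stood apart. On the arm the correlation between genes was estimated at 0.429 with all 6 arrays and 0.108 without wild type replicate 3. The simulation therefore does not show how often camera calls falsely in these data.

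Alternatives were the replicate block, each array left out, no filter and a 60th percentile filter, quantile normalization, median centring, a trended robust eBayes, a pseudocount of 16, other bounds of both segments, all probe sets of a gene, other set tests and other thresholds. Without wild type replicate 3 and DpDf replicate 1 together, without replicate 3 of both groups with the block, and array quality weights were added after the data were seen. Quantile normalization moved the median log2 difference of all probe sets from 0.18 to 0.03. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.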

Results

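The study profiled transcripts in 14-day maize seedlings that segregated for a segmental aneuploidy in the B73 inbred background. DpDf (duplicate-deficient) plants, derived from the translocation T5-6b, carry 3 copies of most of the chromosome 5 short arm and a single copy of the chromosome 6 short arm tip. Their wild-type siblings carry 2 copies of both. RNA came from shoot tips rich in meristem, with leaf primordia attached, and each of the 3 DpDf pools and 3 wild-type pools held 8 plants and was hybridised to 1 Affymetrix maize array. The deposited intensities covered 17621 probe sets besides 113 control probe sets, and the number of arrays limits the precision of every comparison.

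The 6 arrays were not equally alike. Median intensity was 502.8, 506.1 and 492.7 in DpDf replicates 1 to 3 and 497.9, 490.9 and 415.9 in wild type replicates 1 to 3. Wild type replicate 3 stood apart, since its highest Spearman correlation across probe sets with another array was 0.932, whereas the lowest among the other 5 arrays was 0.988. With all 6 arrays this pool raised the median log2 difference (DpDf minus wild type) over all probe sets tested to 0.18, and without it that median was 0.02. A sign of RNA quality, the 3' over 5' signal of control transcripts, also moved with genotype. The signal of the 3' probe set over that of the 5' probe set, averaged over 5 control transcripts, was 1.84 ± 0.73 on the log2 scale in DpDf and 1.07 ± 0.06 in wild type (SD, n = 3 each). All 3 DpDf pools lay above all 3 wild-type pools (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays can give), and DpDf replicate 1 had the highest value, 2.68.

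**Figure D1:**
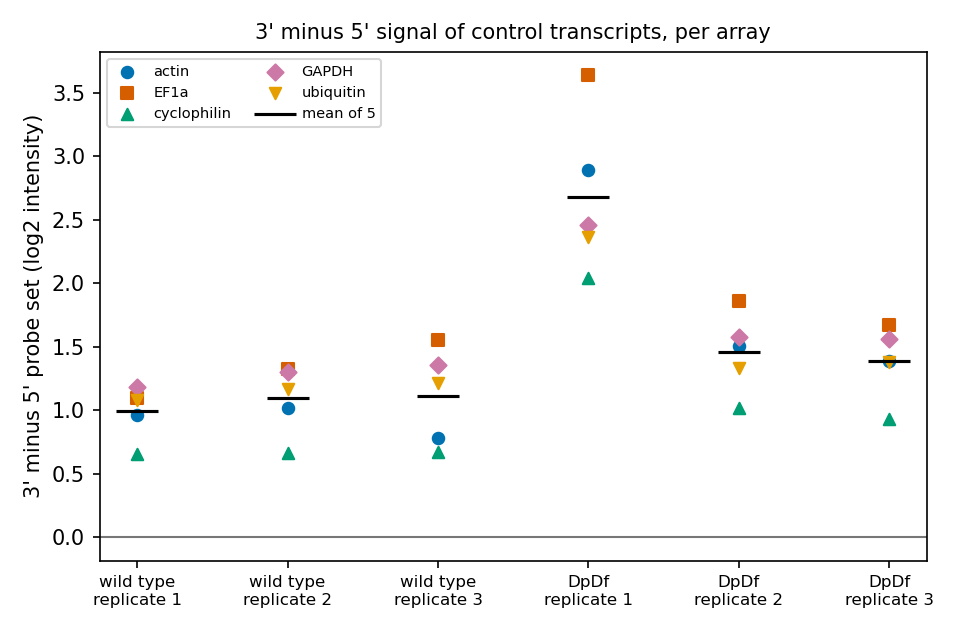
The plot shows, for each array on the horizontal axis, the log2 intensity of the 3' probe set minus that of the 5' probe set for 5 control transcripts (symbols) and their mean (bars). The means lie between 0.996 and 1.12 in the wild-type pools and between 1.39 and 2.68 in the DpDf pools.

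Genes of the chromosome 5 short arm, present in 3 copies in DpDf plants, were higher in DpDf than in wild type. With all 6 arrays the 46 arm genes measured had a median log2 difference of 0.56, against 0.13 in 744 genes elsewhere in the genome. The arm thus lay 0.43 above the other genes (95% bootstrap interval over genes 0.38 to 0.46), a 1.35-fold ratio, and 44 of the 46 genes lay above the median of the others. Without wild type replicate 3 the same quantity was 0.40 (0.34 to 0.44), from a median of 0.40 on the arm and -0.0015 elsewhere. Both intervals lay below 0.585, the log2 of 3 copies over 2. With arm genes not above background in wild type set at their bound (2 and 3 genes), these quantities were 0.42 and 0.38. Array by array, the arm minus the other genes was 0.37, 0.48 and 0.44 in the DpDf pools and 0.05, 0.03 and -0.04 in the wild-type pools, or 0.43 ± 0.06 against 0.01 ± 0.05 (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). Among 11 parts of the genome tested with camera of limma, the arm alone passed, with an adjusted p = 1.05e-17 with all 6 arrays and an adjusted p = 8.19e-22 without wild type replicate 3. This rests on a small preset correlation between genes. With a correlation estimated from so few arrays the arm did not pass in either setting (adjusted p = 0.758 and adjusted p = 0.158). That family of 11 tests was added after the data were seen. Tested alone, as fixed beforehand, the arm passed 0.05 in both settings with the preset correlation, and with the estimated correlation only without wild type replicate 3.

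**Figure D2:**
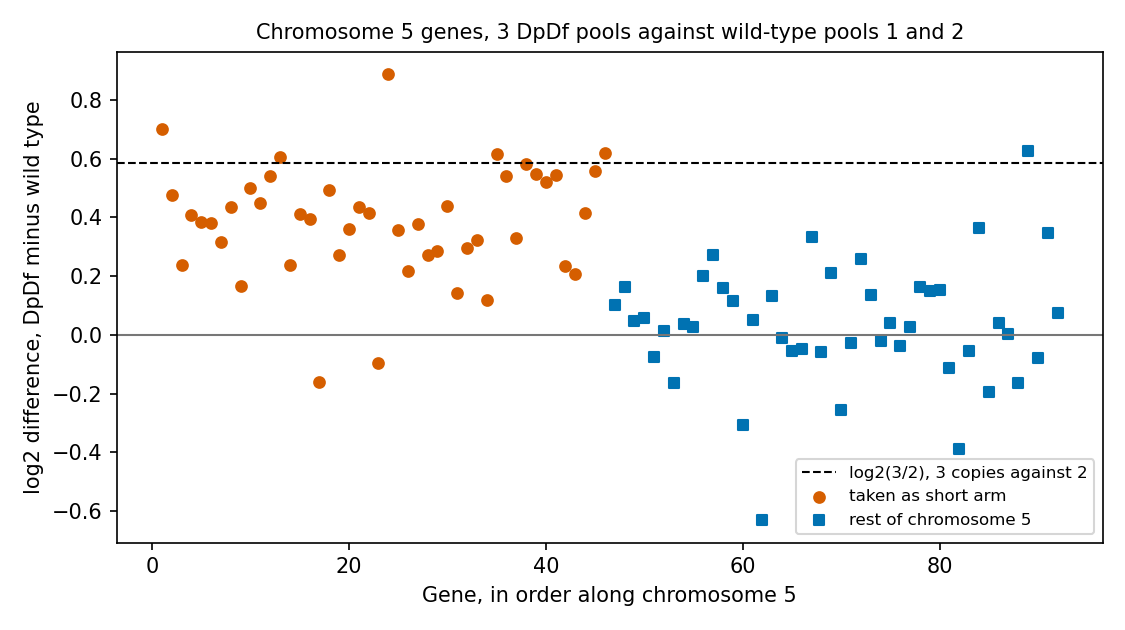
Each point is a gene of chromosome 5 in its order along the chromosome, with the log2 difference between the 3 DpDf pools and wild-type pools 1 and 2 on the vertical axis, and the dashed line is the log2 of 3 copies over 2. The 46 genes taken as the short arm average 0.39, and the other 46 genes of the chromosome average 0.04.

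**Figure D3:**
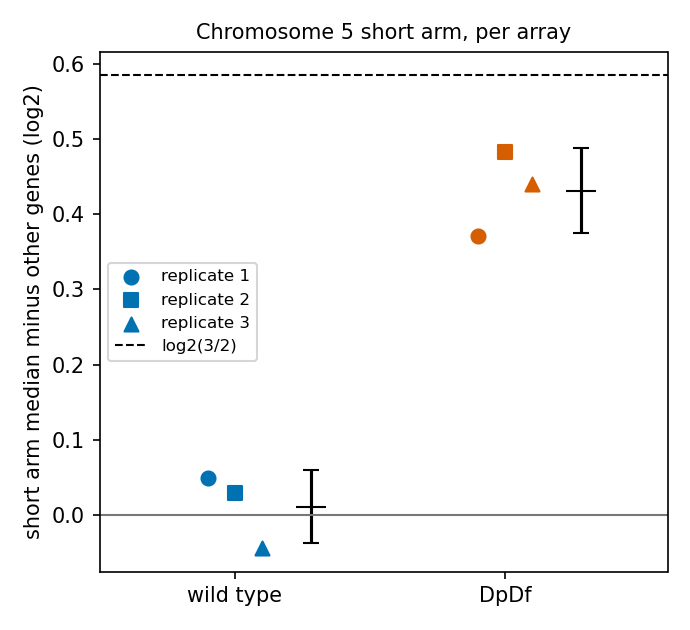
Points are arrays, and the vertical axis gives the median log2 value of the short arm genes relative to the wild-type mean, minus that of the other genes, with the mean and SD of each group (n = 3) beside them. DpDf arrays lie between 0.37 and 0.48, and wild-type arrays between -0.04 and 0.05.

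Other parts of the genome showed no such shift. Without wild type replicate 3, the median differences of the other chromosomes and of the rest of chromosome 5 lay between -0.0534 and 0.0378. Single genes of the arm passed the test of limma in that setting, in which 20 of its 60 probe sets, from 19 genes, had an adjusted p under 0.05, all of them higher in DpDf. Elsewhere 4 of 877 placed probe sets were called higher (Fisher's exact test, two-sided p = 4.12e-22). That test treats probe sets as independent, although some share a gene and all come from the same arrays. Its p therefore leaves out the spread between pools. With all 6 arrays 0 of the 60 were called. Relative to the other genes and without wild type replicate 3, the 95% intervals of 40 of the 46 genes lay above 0, those of 26 included 0.585 and those of 15 lay between both values. With all 6 arrays these counts were 22, 37 and 0, and with quantile normalization 32, 33 and 9. Intervals below 0.585, whether or not they included 0, numbered 20 without wild type replicate 3, 9 with all 6 arrays and 13 with quantile normalization. No interval lay above 0.585 in these 3 settings.

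Among the arm genes that rose without wild type replicate 3, tip3a (LOC541896), which encodes an aquaporin of the vacuolar membrane, had the largest log2 difference, 0.89 ± 0.16 (SE, limma adjusted p = 0.0329). The protein disulfide isomerase gene pdi4 (LOC606412) rose by 0.52 ± 0.08 in the brighter of its 2 probe sets (adjusted p = 0.024), which stands for it in the arm values. The dimmer was not above background in wild type and at least 1.6-fold higher (adjusted p = 0.0158). Whether the probe sets differ in the size of the rise was not tested. With all 6 arrays the brighter lay at 0.96 (adjusted p = 0.458). The gene sig6 (LOC542484), which encodes a sigma factor of the plastid RNA polymerase, rose by 0.70 ± 0.07 (adjusted p = 0.0151). The other genes among the 8 of largest difference were pglcat8 (0.68), the ribosomal protein gene RPL19 (0.62), the calcium-dependent protein kinase gene cdpk1 (0.62), psiP (0.58) and MTK-4 (LOC542152, also listed as TLK2), which was not above background in wild type and at least 1.21-fold higher. The 2 further probe sets of pglcat8 were not called (0.11, adjusted p = 0.521, and 0.14, adjusted p = 0.428), and the latter stands for this gene in the arm values. With all 6 arrays these 2 lay at 0.18 and 0.47. The genes other than pdi4 and MTK-4 had, with all 6 arrays, differences of 0.70 to 0.92, and these genes and MTK-4 had adjusted p-values of 0.302 to 0.329. By the probe set standing for each gene, atGRF2 (-0.16) and RPL10 (-0.10) were the 2 arm genes below the rest of the genome. They were singled out after their values were seen, and neither passed the test. They lay at -0.38 and 0.02 with all 6 arrays, and a further probe set of RPL10 at 0.10 and, with all 6 arrays, 0.26. Further probe sets of his1 (-0.42), cat1 (-0.41) and TCTP (-0.28) were also lower, and none was called. With all 6 arrays they lay at -0.28, -0.04 and -0.15. The probe sets standing for these genes lay at 0.17, 0.33 and 0.24 without wild type replicate 3. The falls of his1 and cat1 came mostly from DpDf replicate 1, the pool of highest 3' over 5' signal. There the lower his1 probe set read 10.89, against 11.931 and 12.021 in DpDf replicates 2 and 3. Wild type replicates 1 and 2 read 12.059 and 12.001. For cat1 these values were 8.047, 8.997, 8.887, 9.052 and 9.062, in the same order. The lower TCTP probe set read 9.73 to 9.855 in DpDf, under 10.093 and 10.057 in those wild-type pools.

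Across the whole array few probe sets passed the test with all 6 arrays. Of 10661 probe sets tested, 3 were called, all higher in DpDf, while 1041 had an unadjusted p under 0.05. A probe set with no gene name here rose by 2.63 ± 0.13 on the log2 scale (SE, limma adjusted p = 0.00106). Another of the same transcript cluster was not above background in wild type and at least 1.7-fold higher in DpDf (adjusted p = 0.000895). The remaining probe set, also unnamed and not above background in wild type, was at least 3.27-fold higher (adjusted p = 0.0251). Among the 3 called, it alone lay under the 40th percentile on all wild-type arrays and above the 60th on all DpDf arrays. The reverse pattern could not occur among them, as all 3 were higher in DpDf. Probe sets not called were not counted for either pattern. The adjusted p of this remaining probe set went above 0.05 when DpDf replicate 1, 2 or 3 or wild type replicate 2 was left out, the highest being 0.256. It did so too with no filter (0.102) and with quantile normalization (0.136). Its bound stayed at 3.14-fold to 3.51-fold with single arrays left out.

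Leaving out wild type replicate 3 raised the number of calls to 355, of which 327 were higher and 28 lower in DpDf, and the 3 probe sets above were among them. Without replicate 3 of both groups and with the replicate number as a block, 4 probe sets were called. Of placed probe sets 0 on the arm and 0 elsewhere passed in that fit, which was added after the data were seen. Only 32 of the 355 carry a single gene name here, 20 on the arm and 12 elsewhere. The 2 unnamed probe sets with the largest falls differed by -1.06 ± 0.15 (SE, limma adjusted p = 0.0195) and by a 2-fold ratio (adjusted p = 0.0247). They differed by -0.71 (adjusted p = 0.523) and -0.62 (adjusted p = 0.562) with all 6 arrays. In tests on simulated data, 38.5% of 2-fold changes and 0% of 1.5-fold changes were recovered with all 6 arrays. Without wild type replicate 3 these shares were 91% and 53%, with 12 and 5 false calls, against 0 with all 6 arrays. Probe sets varied independently in these simulations, which held no 3' over 5' difference between groups. The shares may therefore differ from the power in the real data.

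Outside the arm, genes whose copy number the labels leave at 2 changed in both directions once wild type replicate 3 was left out, with 4 probe sets higher and 8 lower from 11 genes. The 4 genes that rose were saf1 (LOC542388, also listed as In2-1, not above background in wild type and at least 1.17-fold higher), gst42, which encodes a glutathione transferase (0.74 ± 0.13), opr5, a gene of the oxophytodienoate reductase family (0.63 ± 0.12), and LOC542000 (0.43 ± 0.07, SE throughout). Genes that fell were fnr1 (-0.89 ± 0.13), aprl1 (-0.83 ± 0.08), the haemoglobin gene Hb2 (-0.72 ± 0.11), gpc4 and gpc3, which encode cytosolic glyceraldehyde-3-phosphate dehydrogenases (-0.63 ± 0.11 and -0.62 ± 0.11), the elongation factor gene elfa3 (-0.39 ± 0.08) and sbip1b (-0.36 ± 0.07). Their limma adjusted p-values ran from 0.0141 for saf1 to 0.0459 for sbip1b. Further probe sets were not called for gpc3 (-0.30, adjusted p = 0.162), for fnr1 (-0.44, adjusted p = 0.148) and for elfa3 (4 probe sets, -0.11 to -0.14). In the DpDf pools the called probe set of elfa3 read 8.305 to 8.388 on the log2 scale, near the background bounds of 8.3147 to 8.3264. Its 4 further probe sets read 13.981 to 14.743 there. The called probe sets of gpc3 read 10.219 to 10.591, and the uncalled one 12.658 to 12.931. For elfa3 and gpc3 the calls thus cover the dimmer probe sets, not the gene as a whole. In the blocked fit without replicate 3 of both groups none of these genes passed the test, and none did with all 6 arrays. The differences of 7 of them then shrank by over 1.5 times, to -0.53 for fnr1, -0.35 for aprl1, -0.37 for gpc4, -0.02 for gpc3, -0.24 for elfa3, -0.05 for sbip1b and 0.41 for opr5. The other called probe set of gpc3 turned to 0.05. Direction was not kept by gpc3 without DpDf replicate 1 or wild type replicate 1 or 2 (0.06, 0.26 and 0.29), nor by sbip1b without wild type replicate 1 or 2 (0.12 and 0.09), so the fall of both rests on leaving out wild type replicate 3. The pools of DpDf plants in which these genes differed were also those with the larger 3' over 5' signal, by 0.77 on the log2 scale. DpDf replicate 1 raised this value, as the DpDf mean without it was 1.42, against 1.07 in wild type.

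For the tip of chromosome 6, present in 1 copy in DpDf plants, the first 3% of the chromosome held 0 genes that were both named and measured, so no value can be given for the region as it was set. Within the first 6% lay 3 genes, whose differences were -0.07 for the ferredoxin gene fdx2, -0.04 for the fructokinase gene frk2 and 0.12 for the acidic ribosomal protein gene arpp1a with all 6 arrays. Without wild type replicate 3 they were -0.13, -0.09 and -0.10. None passed the test. The labels place the chromosome 6 break by cytology only, so whether these 3 genes lie in the missing segment is not known here.

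Of 25 gene lists fixed beforehand, 10 had at least 5 measured genes, and none of these passed the set test camera after adjustment, with all 6 arrays or without wild type replicate 3. Cell wall, lignin and xylem genes came nearest. Without wild type replicate 3, 12 of 15 members lay above the median of other genes, and their median was 0.21 (camera adjusted p = 0.0749, and adjusted p = 0.81 with an estimated correlation). With all 6 arrays 10 of 15 did, and their median was 0.18 (camera adjusted p = 0.268), only 0.05 above the other genes. The cellulose synthase genes cesa7 (0.29, adjusted p = 0.0996), cesa8 (0.29, adjusted p = 0.118) and cesa6 (0.24, adjusted p = 0.151) belong to this list. Chromatin and small RNA regulators tended the other way, with 7 of 9 members below the median of other genes. Their median was -0.13 without wild type replicate 3 (camera adjusted p = 0.236) and -0.07 with all 6 arrays (camera adjusted p = 0.268). Of its members mez1 lay at -0.25 (-0.20 with all 6 arrays) and nfa101 at -0.28 (0.0002 with all 6 arrays). A probe set of hmg2 lay at -0.26, but the brighter one, which stands for the gene, at -0.02 (0.07 with all 6 arrays). Heat shock proteins and chaperones had a median of 0.33 with all 6 arrays (camera adjusted p = 0.59), with hsp18 at 1.05 ± 0.48 (SE), and one of 0.14 without wild type replicate 3 (camera adjusted p = 0.677). Leaving out DpDf replicate 1, the pool with the highest 3' over 5' signal, brought this list past the threshold at a median of 0.58 (camera adjusted p = 0.00141, and adjusted p = 0.974 with an estimated correlation).

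The other lists differed little from the rest of the genome. Leaf primordium regulators (11 genes) had a median difference of 0.02 without wild type replicate 3, with ocl4 at -0.41 and yab10 at 0.23 (-0.17 and 0.42 with all 6 arrays), and C4 and Calvin cycle enzymes (8 genes) one of 0.03, with pdk1 at 0.41 and pep1 at -0.28 (0.56 and 0.07 with all 6 arrays). Cell cycle and DNA replication genes (10 genes) had a median of -0.05, glutathione transferases and antioxidant enzymes (14 genes, gst42 not among them) one of -0.03, and cuticle and epidermal lipid genes (6 genes) one of 0.04. Benzoxazinoid synthesis (5 genes) had a median of 0.14 and cytokinin genes (6 genes) one of 0.13. For these 7 lists the camera adjusted p-values without wild type replicate 3 were 0.677 or 0.795, and their medians with all 6 arrays lay between 0.0061 and 0.30 (camera adjusted p-values 0.364 to 0.978). No member of any of the 10 lists passed the test over all probe sets in either setting. Adjusted over the list alone, 0 members passed with all 6 arrays, and without wild type replicate 3 the 2 that passed were the cytokinin receptor gene hk2 (0.31) and the response regulator gene RR7 (-0.32), which lay at 0.37 and -0.51 with all 6 arrays. The larger 3' over 5' signal of the DpDf pools, 0.77 on the log2 scale and smaller without DpDf replicate 1, lay beside each of these lists too.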

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

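For wild type replicate 3 the tests of a scaling step, of RNA degradation and of DpDf plants in the pool, and for the short arm the test of cross-hybridization, were chosen after the results were seen.

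The control transcripts, which no comparison of expression used, gave a larger 3' over 5' signal in DpDf than in wild type, by 0.773 on the log2 scale, and for each of the 5 transcripts all DpDf pools lay above all wild-type pools. Without DpDf replicate 1 the DpDf mean was 1.42, against 1.07 in wild type. Lower RNA quality, which was not measured directly here, is a candidate explanation of some calls. As the cause of the short arm shift it is argued against by the arm genes in DpDf replicate 1, the pool of highest 3' over 5' signal. Relative to other genes, they were not higher there than in DpDf replicates 2 and 3 (-0.0641, 95% bootstrap interval -0.115 to -0.0211, against a shift of 0.402). For calls made without wild type replicate 3, the same difference had a median of 0.0197 over the 28 lower and 0.00666 over the 327 higher ones. Both medians lay inside the quartiles of all probe sets (-0.0906 and 0.142), but a call requires a small spread within DpDf, which draws them towards 0 whatever the cause. The quartiles were -0.22 and 0.07 over the lower calls and -0.06 and 0.09 over the higher ones. Some lower calls thus lay lower still in DpDf replicate 1. All 355 calls remained among 753 when DpDf replicate 1 was left out as well. As every DpDf pool exceeds every wild-type pool, RNA quality and genotype cannot be told apart for single calls, and an effect of the aneuploidy itself stays open too. The argument on the short arm covers its 46 genes as a set, not the calls among them.

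Wild type replicate 3 correlated less with every other array, and the count of calls rose from 3 to 355 without it. A monotone scaling or distribution step cannot change rank correlations, and its highest Spearman correlation was 0.932, while more degraded RNA is argued against by its 3' over 5' value of 1.12, since DpDf replicate 1 at 2.68 still correlated at 0.988 or more with the other 4. DpDf plants in this pool are argued against by its short arm, at -0.0666 relative to other genes against 0.32 to 0.435 in the DpDf pools. Weaker or noisier hybridization may account for it and stays open, because its deviation from the other wild-type arrays was 0.432 to 0.594 in all 5 intensity classes, against 0.0688 to 0.0841 between those arrays, and the ratio of 1.38 between dimmest and brightest lies under the bound of 1.5 set beforehand, a bound that noise of equal size at all intensities would not reach. A background or probe summary step that differed for this array could change ranks and was not tested. A biological difference of this pool, such as its tissue make-up, was not tested either.

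The short arm genes rose by less than dose alone would give, 0.402 against 0.585 without wild type replicate 3. Cross-hybridization with other transcripts could lower the rise. Probe sets with an ID ending in _a_at, _s_at or _x_at lay at 0.177 (0.114 to 0.271). The 40 without such a suffix lay at 0.427 (0.37 to 0.498), still below 0.585. These suffixes were not tested apart, nor were the classes matched for brightness. As a probe set without the suffix may still cross-hybridize, the test does not exclude this explanation. Compression of the brightest signals is argued against as the whole cause, since of 3 classes of genes by intensity the middle lay at 0.41 (0.288 to 0.438) and the dimmest at 0.49 (0.418 to 0.544). The brightest class lay lowest, at 0.3254 (0.2075 to 0.3947), so compression may be a part of the cause. Compression over the whole intensity range stays open, as no transcript of known ratio between the pools was used here. Partial compensation of gene dose in the plants stays open as a hypothesis and was not tested.

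There are 10 ways to split 6 arrays into 3 and 3, and 10 to split 5 arrays into 3 and 2, which is too few for a share under 0.05. The real split alone, 1 of 10, called as many as 3 probe sets with all 6 arrays and 355 without wild type replicate 3, and the highest of the other splits called 0 in both.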

How the results depend on the processing

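The fits without wild type replicate 3 and DpDf replicate 1, without replicate 3 of both groups, and with array weights were chosen after the data were seen. The short arm median kept its direction and, at the preset correlation, its camera call in all 18 alternatives, between 0.374 with median centring and 0.655 without wild type replicate 2. That call was lost with an estimated correlation over 11 parts of the genome (adjusted p = 0.758 with all 6 arrays, adjusted p = 0.158 without wild type replicate 3 and adjusted p = 0.995 with the block). Tested alone with an estimated correlation, the arm did not pass with all 6 arrays and passed without wild type replicate 3. Over the 11 parts, fry did not pass for the arm with the block (adjusted p = 0.523). The count of probe sets called was 2 to 355 when single arrays were left out (355 without wild type replicate 3, otherwise 2 or 3) and 2 to 4 in the other settings chosen beforehand, 3 with the replicate block, which changed no call. It was 753 without wild type replicate 3 and DpDf replicate 1, and 2446 with array weights, whose estimation did not converge. Calls on the short arm ranged from 0 to 20 and outside from 0 to 12 with single arrays left out, the highest without wild type replicate 3, and were 32 and 43 without both arrays. Without replicate 3 of both groups and with the block, 4 probe sets were called, 0 on the short arm and 0 outside, although differences stayed about as large in this fit of 4 arrays (arm median 0.396, sig6 0.70, fnr1 -0.84 and aprl1 -0.80, each of these genes with an adjusted p = 0.0851). Gene lists called ranged from 0 to 1 with single arrays left out. The list called without a filter was seed storage and embryo (1 list, adjusted p = 0.00444, with 15 genes in place of 2, and adjusted p = 0.918 with an estimated correlation). Without both arrays 2 were called, heat shock proteins and cell wall, each with an adjusted p = 0.891 with an estimated correlation. Probe sets at background in 1 group only ranged from 0 to 1 with single arrays left out and were 0 without a filter and with quantile normalization. With single arrays left out, gpc3 ranged from -0.62 to 0.29 (0.06 without DpDf replicate 1, 0.26 and 0.29 without wild type replicates 1 and 2) and sbip1b from -0.36 to 0.12 (0.12 and 0.09 without the same wild-type pools), and without wild type replicate 3 and DpDf replicate 1 sbip1b was at -0.38. The cause was not tested, except that fewer dim genes enter under the filter. The chromosome 6 tip held no measured gene and had no value in any alternative except the wider bounds. Signal near background limits dim probe sets.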

Other observations

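The split along chromosome 5 and the oxygen-limitation group were tests chosen after the results were seen.

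Along the gene order of chromosome 5, the best single split of its 92 genes, without wild type replicate 3, left 46 genes before it with a mean log2 difference of 0.39 ± 0.19 (SD over genes) and 46 after it with 0.04 ± 0.21, and it fell in the same place with all 6 arrays. The last gene before it was the ribosomal protein gene RPL19 and the first after it 4CL, named after the values were seen. Resampling the residuals 2000 times put the split between 42 and 49 genes. This may be the breakpoint of the extra segment, as a hypothesis, since the split lies inside the bounds fixed beforehand, and the first gene of the order, sig6, was raised as well. A fit of 1 split does not test whether the rise ends at 1 place, and PPCK1 after it lay at 0.63 (adjusted p = 0.0513).

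Genes of the response to low oxygen may be lower in DpDf, a hypothesis raised by gpc3, gpc4 and Hb2. Of 11 further members of a textbook list, not seen beforehand, 9 lay below the median of other genes without wild type replicate 3, but the unadjusted p-value of camera was 0.22, and the median lay -0.08 from the other genes. Over all 6 arrays 8 lay below, and the median -0.14 from the other genes. Of these members adh2 (0.34) and sus2 (0.39) were higher without wild type replicate 3, and neither was called. With all 6 arrays adh2 lay at 0.37 and sus2 at 0.70. The test did not pass, and with 11 genes it does not exclude a small shift.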
